A study of Mus musculus with 12 samples.

How the data were processed

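RNA abundance was measured in the hypothalamus of adult Pdyn-eGFP-RPL10a mice, which carry a bacterial artificial chromosome that tags the large ribosomal subunit protein RPL10a with green fluorescent protein in prodynorphin (Pdyn) neurons. The procedure, translating ribosome affinity purification, pulls tagged polysomes from a tissue extract with antibodies against the fluorescent protein. Per the labels' protocols, hypothalami were pooled for each sample, an aliquot of the extract was saved as Input RNA, and polysomal RNA was then immunoprecipitated (IP RNA). The mice were wild type or ob/ob on the C57BL/6J strain, aged 3 to 4 months and fed ordinary chow. Ob/ob mice carry a mutation of Lep, the gene for the fat-derived hormone leptin. How many hypothalami went into each pool is not given in the sources used here.

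Biotin-labelled RNA was hybridised to the Affymetrix Mouse Genome 430 2.0 array, per the labels. The deposited values are log2 expression values of GCRMA, which corrects background with probe sequences, quantile normalizes the arrays and summarizes the probes of each probe set, per the submitters' processing notes for the method's name. The software version is not given in the sources used here. The values lie on an absolute log2 scale, with array medians between 3.16 and 3.33. Because GCRMA gives all arrays nearly the same distribution, a difference in total RNA between IP and Input could not be seen. The 2 deposited tables of values differed by at most 0, so 1 was used. The table held 45037 probe sets, none of them a control probe set. Per the labels, the submitters took wild-type IP replicate 1 out because it differed from the other wild-type IP samples, and its column was empty; it was not analysed here.

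Of the probe sets, 35046 were named with 1 gene through the Entrez Gene number in the array annotation and 3084 by the annotation's symbol alone, while 1253 listed several genes and 5654 listed none. The last 2 kinds were left out. For each of the 20753 genes the probe set with the highest mean over all arrays represented the gene, and other probe sets are mentioned where they disagreed. A gene was tested when it reached log2 5 on at least 2 arrays, which left 10887 genes. Positions are those of probe sets on NCBI mouse build 37, as the array annotation gives them; no genome sequence was used here. The files held no detection calls. Where the mean of a group lay under log2 5, the group was treated as near background, and the difference is given as at least N-fold, from the brighter group's mean against log2 5. Single arrays of a near-background group could read above log2 5, so N bounds the difference of group means only. The fitted log2 differences of such genes are given as fitted values, not as sizes of change.

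The groups were wild-type IP (3 samples, 2 with values), wild-type Input (3), ob/ob IP (3) and ob/ob Input (3). Sample titles carry a letter M or F, which the labels do not define. A model with 1 mean per group was fitted to all 11 arrays with limma 3.58.1 in R 4.3.3, with 7 residual degrees of freedom, a prior of 5.04 degrees of freedom and a prior SD of 0.265. Comparisons were IP with Input in each genotype, ob/ob with wild type in IP and in Input, and the difference between genotypes of IP over Input. Tests were 2-sided, with Benjamini-Hochberg adjustment over all genes. A gene was called at an adjusted p under 0.05 and a fold of at least 2 for IP with Input or 1.5 for the others. The folds are those named by the study's design text, which sets no test, so counts by fold alone are given as well. Adjusted p-values of genes are limma's. The labels say that hypothalami were pooled per sample and do not say more on whether the pools were separate, so p-values measure the spread between these samples.

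Within 28 gene lists (neuron classes, other cell types, signalling and cell processes), counts of members are at an adjusted p under 0.05 over all genes, and beside them adjusted over the list alone. The 27 lists with at least 3 tested genes were tested with limma's camera at a preset correlation of 0.01 between genes, and again with an estimated correlation. Pdyn, by whose promoter the neurons were tagged, belongs to 4 of the lists and is counted in each. Named genes were the 10 largest rises and 10 largest falls among the calls of a comparison whose arrays separated the groups, all calls where there were fewer, and the 5 smallest p-values per direction where there was none. Transcripts without a gene name were counted, not named, and some genes that met the rule are not reported here. Pdyn, Rpl10a, Lep, Lepr and 5 genes of the sex chromosomes were always taken, and up to 4 called members per direction of a list. Groups, tests, thresholds, lists, naming rule and alternative settings were chosen before the data were examined.

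Per the labels' protocols, an IP sample and its Input came from 1 pool, and arrays with the same number and genotype were taken as such pairs. Deviations from the group means of same-numbered arrays correlated across genes with r = 0.088 and 0.154 for wild-type replicates 2 and 3, and with -0.091, 0.032 and 0.036 for ob/ob replicates 1, 2 and 3. With Input arrays of another number, the highest r was 0.099 and -0.088 for those wild-type replicates. For those of ob/ob it was 0.116, 0.213 and 0.048, so the values did not show the pairing in most replicates. The consensus correlation of arrays taken as 1 pool was -0.02. The alternatives were the pool as a replicate block, the letter as a covariate, F arrays alone, other filters on low values, other choices of probe set, quantile normalization, a variance trend, only the groups compared, fold alone, other enriched sets and leaving out each array.

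The fit was tested on simulated arrays in which 200 of 10887 genes changed, with noise drawn independently for each gene and array. For ob/ob IP against wild-type IP it recovered 86% of 4-fold changes and 34% of 2-fold changes, with 5 false calls. For the difference between genotypes of IP over Input it recovered 66% of 4-fold changes and 8% of 2-fold changes, with 9 false calls. For IP against Input in wild type it recovered 88% and 22%. A call there also needs a fitted fold of at least 2, which a true 2-fold change often misses. Structure shared between genes or between arrays was not simulated, so the false calls do not cover it. Tables were prepared with Python 3.11.15, pandas 2.3.3 and numpy 2.4.6.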

Results

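The series profiled RNA of hypothalamic prodynorphin neurons and of whole hypothalamus in wild-type and leptin-deficient ob/ob mice. Values were present for 2 wild-type IP, 3 wild-type Input, 3 ob/ob IP and 3 ob/ob Input arrays. Between 16309 and 17156 probe sets per array (36.2% to 38.1%) reached log2 5. The first principal component, 69.2% of the variance, separated IP from Input arrays. The second, 13.4%, spread the Input arrays, from 35.5 for wild-type Input replicate 2 to -56.4 for ob/ob Input replicate 3, with wild-type Input replicate 3 (6.8) and ob/ob Input replicate 1 (6.0) side by side. The letters in the titles matched sex-linked genes: Ddx3y, on the Y chromosome, averaged 11.6 ± 0.247 (SD, n = 3) on M Input arrays and stayed at or below 3.64 on F arrays. Xist, the RNA that silences an X chromosome, averaged 12.1 ± 0.312 (SD, n = 3) on F Input and 5.59 ± 1.24 (SD, n = 3) on F IP arrays, and at most 3.07 on M arrays. The 2 wild-type IP arrays both carried F, while ob/ob IP held 2 M arrays and 1 F array. Lep, the mutated gene, stayed at or below 2.59 on all arrays, so it did not check the genotype labels. Lepr, the leptin receptor gene, stayed at or below 2.86.

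**Figure D1:**
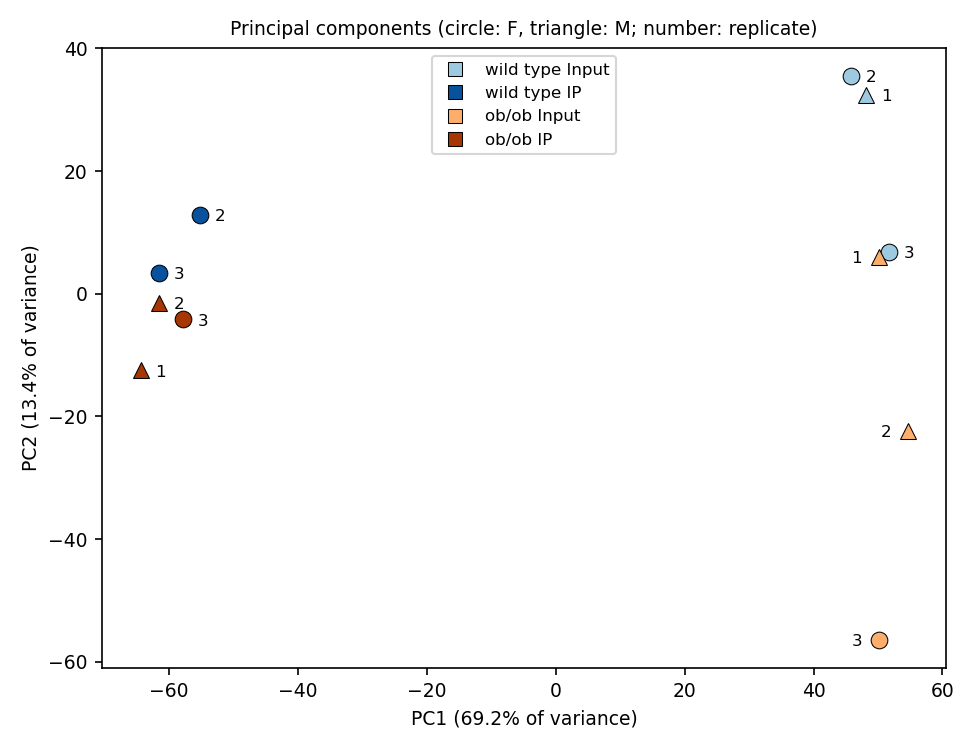
First and second principal components of the 11 arrays over the tested genes (log2 values; axis labels give the percent of variance). Each point is an array, coloured by group, with circles for letter F, triangles for letter M and the replicate number beside it; IP arrays lie left and Input arrays right, and Input arrays spread along the vertical axis.

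The first comparison asked which transcripts were concentrated in the tagged neurons of wild-type mice. Pdyn itself, the precursor of dynorphin opioid peptides (chromosome 2, 129512295 to 129525569), stood at log2 10.09 ± 0.10 in IP (SD, n = 2) and 4.94 ± 0.26 in Input (SD, n = 3), at least 33.9-fold higher (adjusted p = 6.01e-08). Iapp, the gene of the satiety hormone amylin (chromosome 6, 142246947 to 142252345), was at least 311-fold higher in IP by group means, at 13.28 ± 0.29 against 4.66 ± 1.45 (adjusted p = 5.94e-07). Its highest Input array read 5.62, above log2 5, so 311-fold is no bound for single arrays. Without the M array of wild-type Input, the log2 difference of Iapp was 7.79 in place of 8.62. Avp, the vasopressin precursor, was 33.9-fold higher, at 14.72 ± 0.40 against 9.64 ± 0.71. Apoe, the lipid carrier made mostly by astrocytes, was 59.9-fold lower, at 8.83 ± 0.53 against 14.74 ± 0.12. Rpl10a, which encodes the tagged ribosomal protein, did not pass (log2 difference 0.09, adjusted p = 0.693).

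In all, 1083 genes were higher and 1544 lower in IP at 2-fold or more, and 1109 and 1602 by fold alone. The other large rises were Atg7, an enzyme of autophagy (log2 difference 5.54), the chromatin reader Yeats2 (4.48), the neuronal transcription factor Nhlh2 (3.71), and Ralgapa1 (3.70, adjusted p = 0.00982), whose second probe set gave -0.41. Ralgapa1 rested on wild-type IP arrays that lay apart: its difference was 4.59 without replicate 2 and 2.81 without replicate 3, where it did not pass (adjusted p = 0.117). Near background in Input were Prok2, a secreted circadian signal (at least 2.46-fold higher), Ankrd63 (at least 10.4-fold) and the forebrain transcription factor Fezf2 (at least 8.85-fold). On the lower side, ND5, a subunit of respiratory complex I encoded by the mitochondrial genome, differed by -6.70, and the zinc transporter gene Slc39a12 by -5.49, with -0.97 at another probe set. Genes of vessels and glia lay near background in IP: the thyroid hormone transporter gene Slco1c1 was at least 20.7-fold lower, Slco1a4 at least 19.5-fold, the matrix protein gene Vtn at least 23.2-fold and Tm4sf1 at least 12.3-fold. Fxyd1, a regulator of the sodium pump, was at least 13.4-fold lower, the proteoglycan gene Sdc4 at least 17.3-fold and Prom1 at least 9.90-fold. The wild-type IP mean rested on 2 arrays, both F.

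Marker lists separated neurons that use dynorphin from glia and vessels. All 6 orexin neuron genes were higher in IP (6 adjusted over the list alone, median 2.28), among them Hcrt, the orexin precursor, at 13.72 ± 0.14 against 10.60 ± 0.60. Another of them, the transcription factor Lhx9 (2.57), had a second probe set at 0.77. The list passed (camera adjusted p = 5.64e-06, and adjusted p = 0.0204 with an estimated correlation). Of 7 magnocellular and paraventricular genes, 6 were higher and 1 lower (6 and 1 adjusted over the list alone, median 2.59). They included Avp and Oxt, the oxytocin precursor (2.60), against the sodium channel gene Scn7a (-2.29), with camera adjusted p = 0.00102 and adjusted p = 0.0784 with an estimated correlation. Of 8 genes of arcuate kisspeptin neurons, known as KNDy cells, 4 were higher and none lower (4 and 0 adjusted over the list alone), Pdyn, Nhlh2, the neurokinin B precursor Tac2 (2.94) and the estrogen receptor Esr1 (1.67). That list had camera adjusted p = 0.00716 and adjusted p = 0.0842 with an estimated correlation. Kiss1, the kisspeptin gene, was on the fixed list but had no probe set assigned to it, so it was not measured. All 12 astrocyte genes were lower (12 adjusted over the list alone, median -3.92), such as the water channel Aqp4 (-4.76), with camera adjusted p = 1.32e-11 and adjusted p = 0.0842 with an estimated correlation. Of 13 oligodendrocyte genes 10 were lower (11 adjusted over the list alone), including the myelin gene Mobp (-4.66), with camera adjusted p = 2.97e-08 and adjusted p = 0.0703 with an estimated correlation.

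Microglia genes were lower in 10 of 11 cases (10 adjusted over the list alone), such as the complement gene C1qb (at least 21.4-fold), with camera adjusted p = 2.31e-10 and adjusted p = 0.0204 with an estimated correlation. All 7 endothelium and pericyte genes were lower (7 adjusted over the list alone), including the tight junction gene Cldn5 (at least 19.6-fold), with camera adjusted p = 5.64e-06 and adjusted p = 0.0784 with an estimated correlation. Of 8 tanycyte and ependyma genes 6 were lower and 1, the thyroid hormone binding protein gene Crym (1.66), higher (6 and 1 adjusted over the list alone), with camera adjusted p = 0.00208 and adjusted p = 0.0842 with an estimated correlation. Among other hypothalamic neuropeptides, 6 of 19 were higher and 7 lower (6 and 8 adjusted over the list alone; camera adjusted p = 0.773). Pomc, the melanocortin precursor (2.80), Gal, galanin (2.26), and Cartpt, the precursor of the satiety peptide CART (2.17), stood against Pmch, the melanin-concentrating hormone precursor (-2.17), and Adcyap1 (-1.93). Agrp, the hunger peptide of arcuate neurons, was at least 2.61-fold lower.

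Immediate early genes were higher in 7 of 9 cases (7 adjusted over the list alone), among them Fosl2 (3.47), Egr2 (2.85) and Fos (1.75), with camera adjusted p = 0.0012 and adjusted p = 0.131 with an estimated correlation. Nuclear-encoded respiratory chain genes were higher in 29 and lower in 4 of 72 cases (30 and 4 adjusted over the list alone, median 0.43), for example Ndufs4 (1.16), with camera adjusted p = 0.000124 and adjusted p = 0.446 with an estimated correlation. Of 19 channel genes, 8 were lower and 1 higher (9 and 1 adjusted over the list alone), among them the potassium channel Kcna1 (-1.86), with camera adjusted p = 0.0247 and adjusted p = 0.405 with an estimated correlation. Pan-neuronal genes did not move as a list: 1 was higher and 2 lower of 13 (1 and 2 adjusted over the list alone, median -0.17, camera adjusted p = 0.59).

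**Figure D2:**
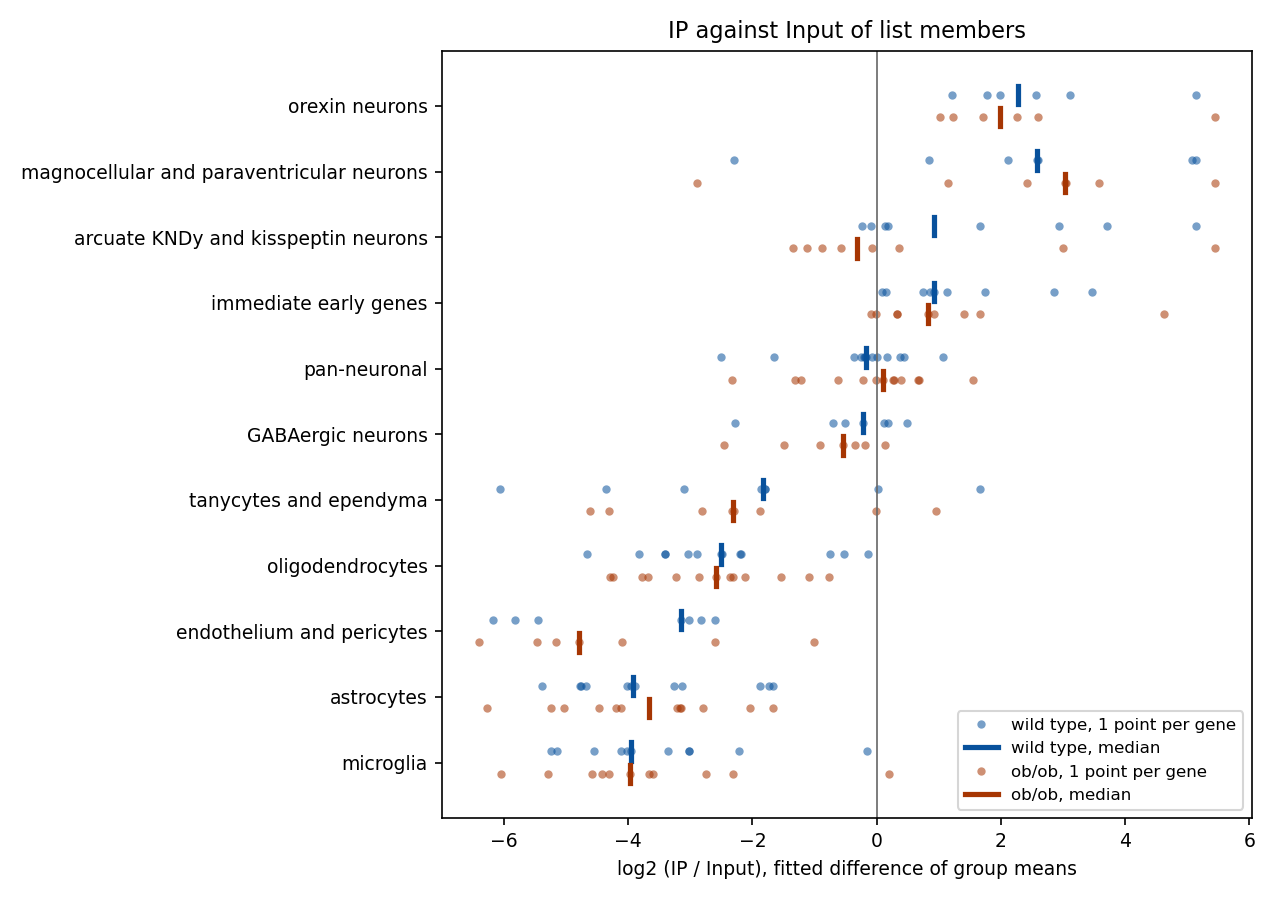
Fitted log2 difference of IP and Input for the members of 11 gene lists in wild type (blue) and ob/ob (brown). Each point is a gene and each vertical bar the list's median; orexin genes lie right of 0 in both genotypes (medians 2.28 and 1.99), and astrocyte and microglia medians lie below -3.6.

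The same comparison in ob/ob mice gave 1088 higher and 1815 lower genes (1102 and 1831 by fold alone). Pdyn was at least 37.1-fold higher in IP, at 10.21 ± 0.19 against 4.77 ± 0.45 (SD, n = 3 each, adjusted p = 1.21e-08). Akr1b8, an aldo-keto reductase, followed (at least 21.5-fold), with the transcription factor Fosl2 (log2 difference 4.62), the cell cycle gene Cks1b (4.02), the growth factor Fgf7 (3.96), Yeats2 (3.96), the nicotinamide-methylating enzyme Nnmt (3.77) and the translation factor Eif4e3 (3.73). Fezf2 was at least 12.2-fold and Klhl30 at least 3.37-fold higher. Lower in IP were the matrix gene Sparc (-6.31), Ntsr2, a neurotensin receptor of astrocytes (-6.28), Apoe (-6.13), Slc39a12 (-5.90) and ND5 (-5.75). Near background in IP were Sdc4 (at least 39.2-fold lower), Gpr37l1 (at least 52.1-fold), Vtn (at least 25.3-fold), Fxyd1 (at least 16.2-fold) and C1qa (at least 10.8-fold). Rpl10a again did not pass (0.19, adjusted p = 0.332).

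The calls of the genotypes, which share no array, had 628 higher and 1212 lower genes in common, against 108.2 and 257.4 for independent lists, and 1 gene was called in opposite directions. Differences correlated across genes with Pearson's r = 0.871 and Spearman's rho = 0.823; genes are not independent replicates. In ob/ob all 6 orexin genes were higher (6 adjusted over the list alone; camera adjusted p = 3.02e-05, and adjusted p = 0.0297 with an estimated correlation). Of 11 microglia genes 10 were lower (10 adjusted over the list alone), with camera adjusted p = 2.4e-08 and adjusted p = 0.0297 with an estimated correlation. All 12 astrocyte genes (12 adjusted over the list alone) and all 13 oligodendrocyte genes (13 adjusted over the list alone) were lower, with camera adjusted p = 4.51e-10 and 3.26e-08, and adjusted p = 0.111 and 0.0711 with an estimated correlation. Glucocorticoid-responsive genes were lower in 7 and higher in 1 of 12 cases (7 and 1 adjusted over the list alone). They included the metallothionein Mt2 (-3.64) and Tsc22d3 (-3.59) against the chaperone Fkbp5 (0.89), with camera adjusted p = 0.0159 and adjusted p = 0.202 with an estimated correlation. Cytosolic ribosomal protein genes were higher in 19 and lower in 3 of 43 cases (19 and 3 adjusted over the list alone, median 0.35), with camera adjusted p = 0.00378 and adjusted p = 0.367 with an estimated correlation, and 0.053 after quantile normalization. Of 7 magnocellular and paraventricular genes, 6 were higher and 1 lower, as many adjusted over the list alone (median 3.04), with camera adjusted p = 0.000641 and adjusted p = 0.0847 with an estimated correlation. All 7 endothelium genes were lower (7 adjusted over the list alone, median -4.80), with camera adjusted p = 5.69e-05 and adjusted p = 0.111 with an estimated correlation. Of 8 tanycyte genes 6 were lower and 1 higher (6 and 1 adjusted over the list alone), with camera adjusted p = 0.00378 and adjusted p = 0.111 with an estimated correlation.

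Immediate early genes were higher in 5 of 9 cases in ob/ob (5 adjusted over the list alone), with camera adjusted p = 0.00655 and adjusted p = 0.203 with an estimated correlation, and 0.0812 with no filter. Respiratory chain genes were higher in 30 and lower in 5 of 72 cases (30 and 5 adjusted over the list alone), with camera adjusted p = 3.32e-05 and adjusted p = 0.338 with an estimated correlation. Channel genes were lower in 10 of 19 cases (10 adjusted over the list alone), with camera adjusted p = 0.0115 and adjusted p = 0.295 with an estimated correlation. The KNDy list did not pass in ob/ob (camera adjusted p = 0.77): Pdyn and Nhlh2 (3.01) were higher, the neurokinin receptor Tacr3 (-1.35), Prlr (-1.11) and Pgr (-0.57) were among the lower genes, and its median (-0.32) and mean (0.60) differed in sign. As many members passed adjusted over the list alone, 2 higher and 4 lower.

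The study's second question was which transcripts of these neurons differ with leptin deficiency. Iapp was near background in ob/ob IP, at 3.37 ± 0.32 (SD, n = 3), against 13.28 ± 0.29 in wild-type IP (SD, n = 2), at least 311-fold lower (adjusted p = 8.61e-06). Its 3 other probe sets gave log2 differences from -5.41 to -10.16. Cartpt (chromosome 13, 100668437 to 100670608) was 6.79-fold lower, at 9.38 ± 0.26 against 12.14 ± 0.02 (adjusted p = 0.00014). Pomc was 6.92-fold lower, at 11.62 ± 0.62 against 14.41 ± 0.12 (adjusted p = 0.0142), and Tac2 5.24-fold lower, at 8.93 ± 0.32 against 11.32 ± 0.04 (adjusted p = 0.0165). Pdyn did not pass, at 10.21 ± 0.19 against 10.09 ± 0.10 (log2 difference 0.13, adjusted p = 0.943), nor did Rpl10a (0.17, adjusted p = 0.832).

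Of 10887 genes, 89 were called, 19 higher and 70 lower in ob/ob IP, 6 of them without a gene name; by fold alone the counts were 314 and 842. Inhbb, which encodes a subunit of activin and inhibin, was at least 7.47-fold lower (adjusted p = 0.000456). Its fitted log2 difference was -5.19 without wild-type IP replicate 2 and -3.69 without replicate 3, against -4.44, and it passed in both. The activity-regulated transcription factor Egr3 was 7.75-fold lower, Ankrd63 6.41-fold, and Ppp1r1b, the phosphatase inhibitor DARPP-32, at least 4.34-fold. Socs2, a feedback inhibitor of cytokine signalling, was at least 4.12-fold lower. Akr1b8 was 4.32-fold higher, at 9.43 ± 0.34 against 7.32 ± 0.23 (adjusted p = 0.0172), Ddah2 2.73-fold, the plasma retinol carrier gene Rbp4 2.72-fold, and the non-coding RNA Pvt1 2.65-fold. Cela1 was 2.41-fold and Kcnmb4os2 2.31-fold higher. Near background in wild-type IP were the salivary amylase gene Amy1 (at least 2.36-fold higher), Dnmt3l, a cofactor of DNA methylation (at least 1.56-fold), Cyb5r2 (at least 1.28-fold) and the neuropeptide B precursor Npb (at least 1.02-fold, adjusted p = 0.0499).

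**Figure D3:**
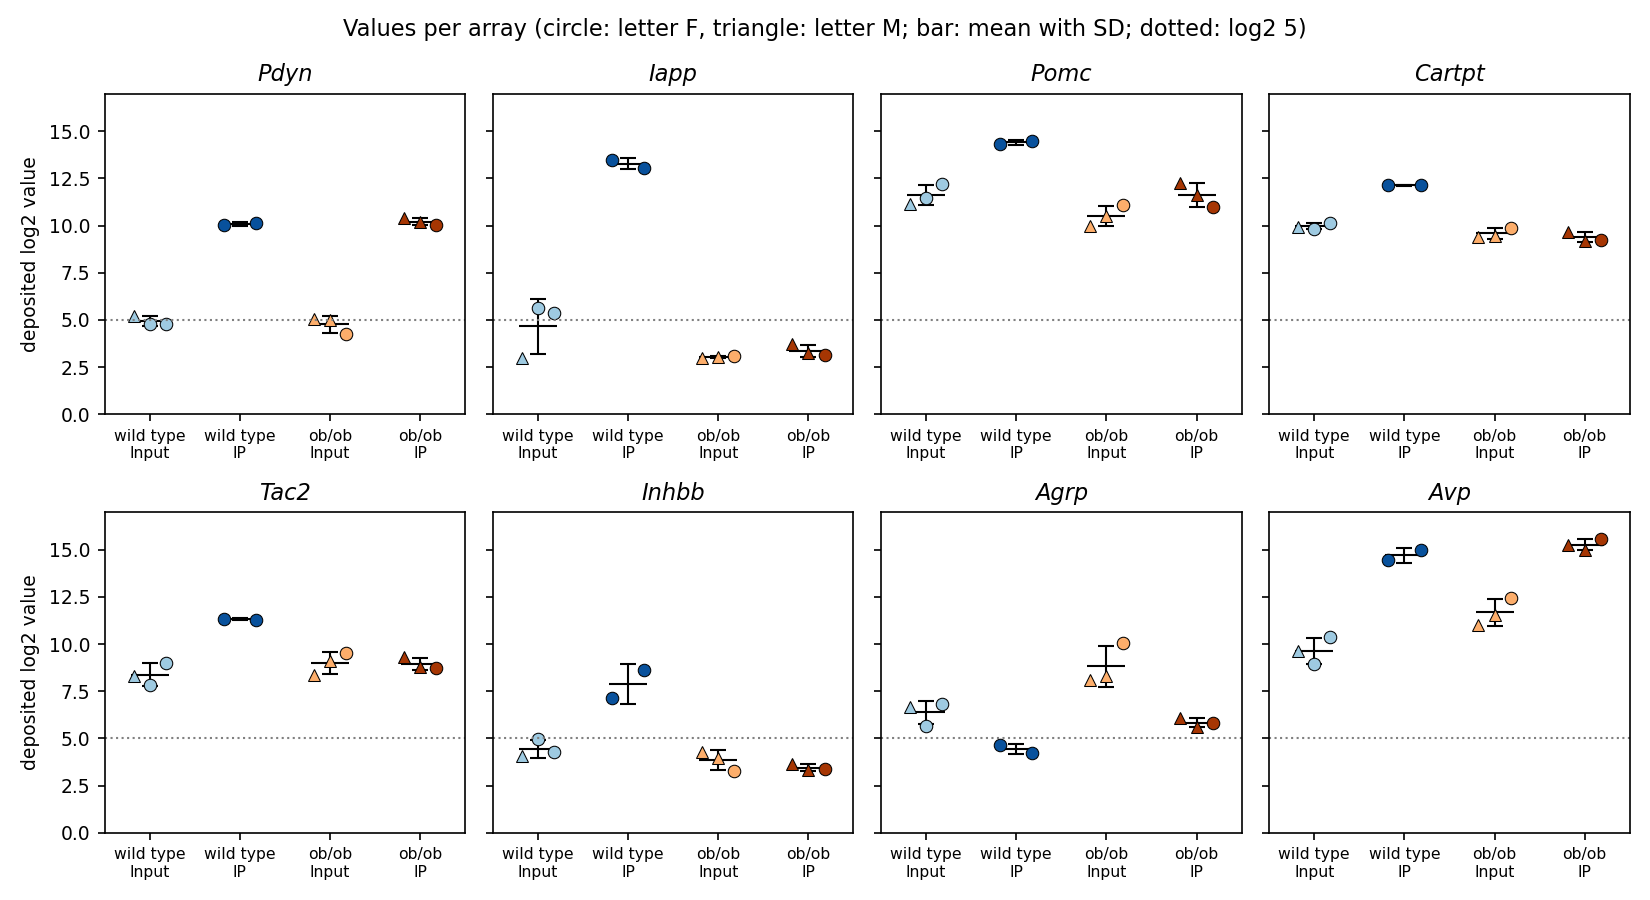
Deposited log2 values of 8 genes on each of the 11 arrays, by group (circles for letter F, triangles for letter M; bars give mean and SD; the dotted line marks log2 5). Iapp lies at 13.1 to 13.5 on the wild-type IP arrays and at or below 3.74 on all ob/ob arrays, and Pdyn differs little between genotypes in IP.

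For Iapp, wild-type Input read 3.00 on the M array and 5.62 and 5.37 on the F arrays, and all ob/ob arrays lay between 3.00 and 3.74, the F arrays included (3.14 in IP and 3.08 in Input). The only M array of wild-type mice was thus as low as ob/ob, and no M array of wild-type IP had values. With the letter as a covariate 9 genes were higher and 34 lower, and between F arrays alone, where ob/ob IP has 1 array and borrows its spread from the other groups, 2 and 12. Iapp, Inhbb, Pomc, Cartpt, Egr3, Ankrd63 and Dnmt3l passed between F arrays, while Tac2 (-2.59) had adjusted p = 0.0928 there and 0.0478 with the letter as a covariate. When only the IP arrays entered the fit, 5 genes were called, 0 higher and 5 lower, so none of the named rises passed there. With the letter as a covariate Amy1 (adjusted p = 0.0982), Npb (0.15), Ddah2 (0.143), Rbp4 (0.11) and Cela1 (0.0968) did not pass. Akr1b8 (0.0127), Cyb5r2 (0.0247), Dnmt3l (0.014), Pvt1 (0.0478) and Kcnmb4os2 (0.0422) passed with it. After quantile normalization of the 11 arrays the split was 17 higher and 31 lower. Without wild-type IP replicate 2 or 3, 17 and 20 genes were called, without ob/ob IP replicates 1 and 2, 44 and 33; Pomc had log2 differences of -2.88 and -2.70 (adjusted p = 0.0926 and 0.0944) without wild-type IP replicates 2 and 3, and Tac2 -2.36 and -2.42 (0.14 and 0.105). Egr3 (0.15 and 0.0752) and Ankrd63 (0.175 and 0.193) did not pass there either, nor with only the IP arrays (0.158 and 0.238), and Dnmt3l did not pass without replicate 3 (0.0908) or with only the IP arrays (0.141). With a lone array in the wild-type group, the spread is likewise assumed to be that of the other groups.

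Of 1083 genes higher in IP than Input in wild type, 79 differed between genotypes when adjusted over these genes alone, 12 higher and 67 lower in ob/ob IP (84.8% lower), and 37 adjusted over all genes, 7 higher and 30 lower. By fold alone 45 were higher and 193 lower. The set was chosen on the same wild-type IP arrays, so its direction is not independent evidence. In 100 simulated data sets with no genotype difference in IP, a test chosen after seeing the data, a median of 78.1% of set members at an unadjusted p under 0.05 and 1.5-fold were lower, against 80.3% here, but there were 51.3 such genes on average against 183 here. Chosen on ob/ob arrays instead (1088 genes), a choice that favours higher genes, the set gave 37 calls, 22 higher and 15 lower. Chosen on the mean of both genotypes (990 genes), it gave 26 higher and 41 lower (61.2% lower).

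KNDy genes were the list with the clearest shift between genotypes. Of 8 genes 3 were lower in ob/ob IP (7 adjusted over the list alone, median -1.19): Tac2, Esr1 (-1.36, adjusted p = 0.0255) and Tacr3 (-1.15, adjusted p = 0.0171). The list had camera adjusted p = 5.82e-08 and adjusted p = 0.0206 with an estimated correlation. Among leptin signalling and energy balance genes, Pomc and Cartpt were the 2 lower of 19 (7 lower and 2 higher adjusted over the list alone), with camera adjusted p = 0.00589 and adjusted p = 0.183 with an estimated correlation. Socs3, a target of leptin signalling, read 4.67 ± 0.61 against 6.18 ± 0.30 and did not pass (adjusted p = 0.184), nor did Agrp (5.84 ± 0.23 against 4.45 ± 0.28, adjusted p = 0.318). Immediate early genes held 2 lower of 9 (3 adjusted over the list alone), Egr2 (-1.47) and Egr1 (-1.42), with camera adjusted p = 0.00293 and adjusted p = 0.231 with an estimated correlation. Other hypothalamic neuropeptides held 2 lower of 19, again Pomc and Cartpt (7 lower and 2 higher adjusted over the list alone), with camera adjusted p = 0.0144 and adjusted p = 0.3 with an estimated correlation. That list did not pass with the letter as a covariate (adjusted p = 0.0748), and without wild-type IP replicate 2 neither it (0.167) nor the immediate early genes (0.0666) passed. Opioid genes held 1 lower of 6, Pomc (3 adjusted over the list alone), with camera adjusted p = 0.00208 and adjusted p = 0.103 with an estimated correlation.

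Some lists passed with no member called over all genes. GABAergic genes had 4 of 7 lower adjusted over the list alone, for example the vesicular transporter Slc32a1 (-0.76), with camera adjusted p = 0.00197 and adjusted p = 0.183 with an estimated correlation. Oligodendrocyte genes had 4 of 13 lower adjusted over the list alone (median -0.55), with camera adjusted p = 0.00222 and adjusted p = 0.246 with an estimated correlation. Axon growth and synaptic genes had 4 of 12 lower adjusted over the list alone, for example Syt4 (-0.89), with camera adjusted p = 0.00446 and adjusted p = 0.183 with an estimated correlation. Circadian clock genes had 2 of 12 lower adjusted over the list alone, for example Bhlhe40 (-0.91), with camera adjusted p = 0.0247 and adjusted p = 0.25 with an estimated correlation. The clock genes did not pass without wild-type IP replicate 2 (0.109) or ob/ob IP replicate 2 (0.142). Ribosomal protein genes lay higher (median 0.17; 1 of 43 higher adjusted over the list alone), with camera adjusted p = 3.13e-06 and adjusted p = 0.25 with an estimated correlation, and adjusted p = 0.086 with fry. For glutamatergic, glucocorticoid, endoplasmic reticulum stress and respiratory chain lists, none of which passed, the median and mean were below 0 and the test pointed up. Beside these shifts, 43 glial and vascular markers had a median of -0.31 in ob/ob IP.

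**Figure D4:**
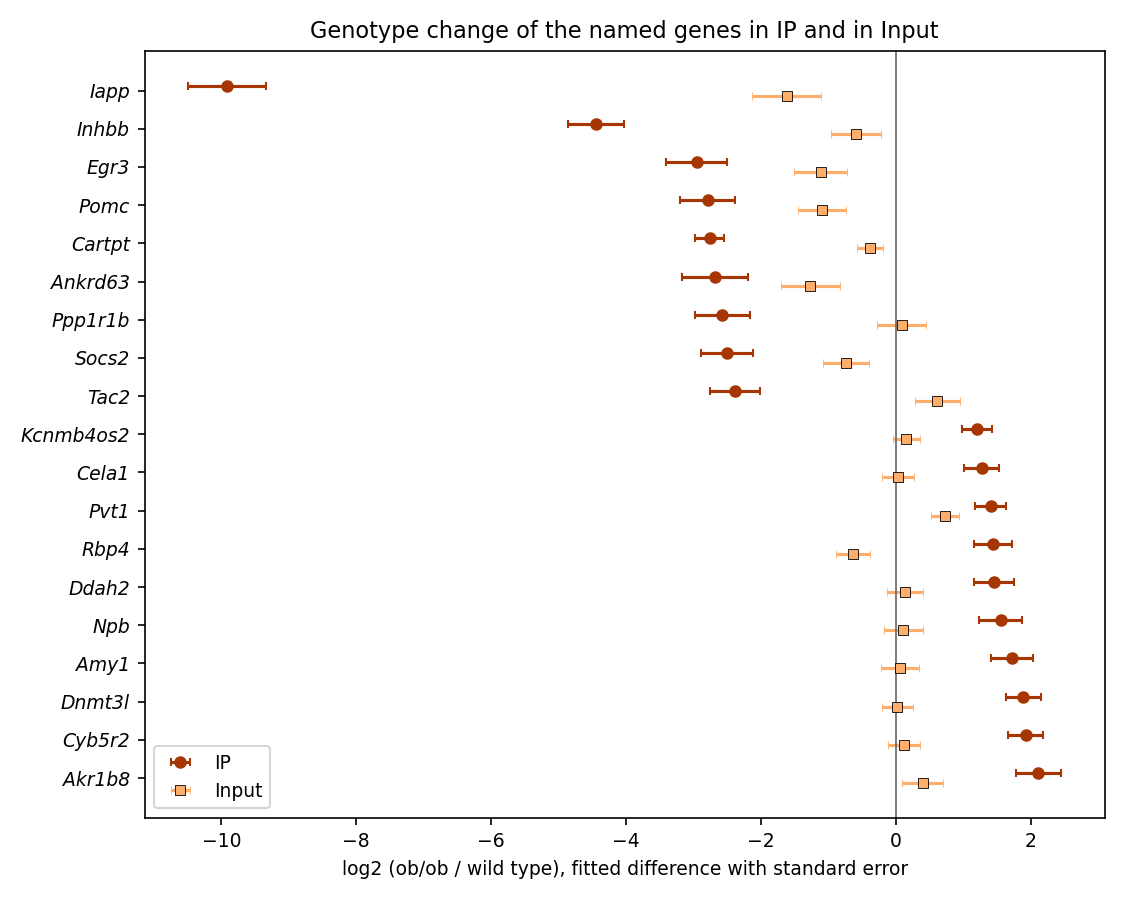
Fitted log2 difference between ob/ob and wild type, with its standard error, for the genes named in the IP comparison, in IP (brown circles) and in Input (orange squares). Iapp differs by -9.91 in IP and Tac2 by -2.39, and the values in Input lie nearer 0.

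In whole hypothalamus, Agrp was 5.38-fold higher in ob/ob, at 8.81 ± 1.07 against 6.39 ± 0.62 (SD, n = 3 each, adjusted p = 0.0432; 1.81 on the log2 scale and not passing without ob/ob Input replicate 3), and Avp 4.13-fold higher, at 11.68 ± 0.72 against 9.64 ± 0.71 (adjusted p = 0.0478). Tspan15, a tetraspanin, was at least 1.68-fold higher (adjusted p = 0.00324). Lower in ob/ob were Anxa3, an annexin (at least 3.08-fold, adjusted p = 0.0398), Gabra4, a GABA receptor subunit (3.60-fold), and the endothelial receptor gene Adgrl4 (3.36-fold). Npy, coexpressed with Agrp in arcuate neurons, read 9.70 ± 0.82 against 8.36 ± 0.20 and did not pass (adjusted p = 0.0597), nor did Pomc (10.52 ± 0.54 against 11.61 ± 0.55, adjusted p = 0.0909).

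The test called 47 genes, 23 higher and 24 lower, against 1061 and 1366 by fold alone. The other named genes were Tmem81 (at least 3.44-fold higher), the cold-inducible RNA-binding protein gene Cirbp (3.66-fold), Pwwp3a (3.36-fold), Arf5 (3.35-fold), Prr3 (3.26-fold), Pabpc4 (2.62-fold) and the complement protease gene Masp1 (at least 1.66-fold). Lower were Apaf1, the apoptosome scaffold (at least 2.82-fold), Hps3 (2.90-fold), the microtubule-severing gene Katna1 (at least 2.80-fold), Rasgrp1 (2.83-fold, with -0.52 and 0.24 as log2 differences at its other probe sets), Tm4sf1 (2.78-fold), Lrp4 (at least 1.84-fold) and Rassf3 (at least 1.17-fold). Of 27 lists 0 passed with camera, 4 had an unadjusted p under 0.05, and 0 passed with the rotation test fry. Zbtb16, a glucocorticoid-induced transcription factor, was the list member called beside Agrp, Avp and Tm4sf1 (at least 1.81-fold higher). The count moved with single arrays and with the letter: without ob/ob Input replicates 1, 2 and 3 it was 2460, 2 and 4, without wild-type Input replicates 1, 2 and 3 it was 2, 1 and 576, and with the letter as a covariate 1318. When only the Input arrays entered the fit 0 genes were called by limma, with 2760 at an unadjusted p under 0.05. The calls in IP and in Input shared 1 gene, against 0.38 for independent lists, and differences between genotypes correlated across genes with r = 0.259.

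The last comparison asked which transcripts differed between genotypes in IP relative to Input. Iapp differed most: IP over Input was 8.62 on the log2 scale in wild type and 0.33 in ob/ob, a difference of -8.29 (SE 0.775, adjusted p = 0.00182). Inhbb (-3.86), Cartpt (-2.38), Ctla2a, a cathepsin inhibitor gene (-2.26), and Npr3, the natriuretic peptide clearance receptor (-2.17), were higher in wild-type IP than Input and not in ob/ob. Tspan15 (-2.27) was lower in ob/ob IP than Input, with IP near background in both genotypes. Iapp and Inhbb lay near background in every group but wild-type IP. Limma called these 6 genes, all lower, and 0 higher, with 490 higher and 855 lower genes at an unadjusted p under 0.05. The highest-ranked positive differences did not pass: Rbp4 (2.08, adjusted p = 0.0606), Pigbos1 (1.65), F11r (1.36), Lrp4 (1.96) and Dnmt3l (1.87). Pdyn had a difference of 0.30 (adjusted p = 0.727) and Rpl10a of 0.09 (adjusted p = 0.877).

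The KNDy list was lower (camera adjusted p = 0.000398, and adjusted p = 0.124 with an estimated correlation), with 0 of 8 members called over all genes and 3 lower adjusted over the list alone; Tac2 had adjusted p = 0.0538. Leptin signalling genes and other neuropeptides held 1 lower of 19 each, Cartpt (4 lower adjusted over the list alone in each), both with camera adjusted p = 0.0103, and adjusted p = 0.304 and 0.484 with an estimated correlation. The neuropeptides did not pass with fry (0.109) or without wild-type IP replicate 2 (0.104). Axon growth and synaptic genes had 1 of 12 lower adjusted over the list alone (camera adjusted p = 0.0158, and adjusted p = 0.369 with an estimated correlation), and did not pass without wild-type Input replicate 3 (0.0535) or ob/ob Input replicate 1 (0.106). With the pool as a replicate block, which pairs IP with Input and so drops wild-type Input replicate 1, 1 gene remained called, Iapp (-7.46, adjusted p = 9.4e-05), and Cartpt (-2.37) had adjusted p = 0.227; leaving out that array alone kept 4 calls. Without ob/ob Input replicate 1, 40 genes were called, and without wild-type IP replicate 3, 1.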

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

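The tests of the letters and of scaling in the IP comparison, of IP purity and of other splits of the Input arrays were chosen only after the result was seen, and those of the letters replaced a planned test on the called genes.

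For 6 genes, IP over Input differed between genotypes by a test of the difference itself, which is why they are listed here. Iapp differed by -8.292 on the log2 scale (SE 0.775, adjusted p = 0.00182), with 8.617 in wild type and 0.325 in ob/ob. Inhbb differed by -3.856 (adjusted p = 0.0345; 3.464 and -0.392), Cartpt by -2.382 (adjusted p = 0.0144; 2.172 and -0.211), Ctla2a by -2.26 (adjusted p = 0.0306; 2.274 and 0.014) and Npr3 by -2.17 (adjusted p = 0.0144; 1.863 and -0.308). Tspan15 differed by -2.272 (adjusted p = 0.0381, with -0.494 and -2.766). Its wild-type Input and both IP groups lay near background, so this difference rests on its higher value in ob/ob Input. Iapp and Inhbb lay near background in wild-type Input and in both ob/ob groups, so their differences rest on the wild-type IP arrays. Iapp had the same direction at its 3 other probe sets (-4.553 to -8.818). IP and Input of a number were taken to share a pool. With the pool as a replicate block Iapp alone stayed called (adjusted p = 9.4e-05), while Inhbb (-3.666), Cartpt (-2.365) and Npr3 (-2.213) had adjusted p = 0.227, Tspan15 (-2.544) 0.174 and Ctla2a (-2.259) 0.306. The differences stayed about as large, and that fit also drops wild-type Input replicate 1, which has no IP partner with values; leaving out that array alone kept 4 of the 6 calls.

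More genes were lower (70) than higher (19) in ob/ob IP than in wild-type IP, and after quantile normalization over 11 arrays 64.6% of calls were lower (31 of 48, confidence interval 49.5% to 77.8%), so scaling stays open as a source of the excess. With the letter as a covariate 79.1% of calls were lower (34 of 43, confidence interval 64% to 90%) against 78.7%, while Input calls went from 47 to 1318. Both intervals treat called genes as independent trials, which they are not, so neither decides the source of the excess. With that covariate Iapp (-9.421), Inhbb (-4.527), Pomc (-2.661) and Cartpt (-2.688) still passed. For these genes that argues against an effect of the letters that IP and Input share as the whole cause. An effect in IP alone stays open, since no M array of wild-type IP has values: over 80 genes called without the F array of ob/ob IP that array's change was 0.701 of that of the M arrays, but noise in the shared wild-type IP arrays alone would give 0.5, and the planned version over the called genes (median 1.341 against 1.389) had a like fault. More glial or vascular RNA in ob/ob IP would raise markers of those cells, but 43 glial and vascular markers had a median of -0.31, with 35 below 0. Some of these markers lay near background in IP, and RNA carried over from other neurons was not tested. Among genes enriched in wild-type IP 84.8% of calls were lower, against 61.2% (41 of 67) with the set chosen on the mean of both genotypes and 40.5% (15 of 37) with it chosen on ob/ob arrays, which met the planned criterion but favours higher genes by its own construction, so how much of the excess came from the choice stays open, as does a biological effect of leptin deficiency.

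Input calls came from arrays spread along a single axis, with ob/ob Input replicate 3 farthest out. Without that array 2 of 47 calls remained, a share of 0.043, which met the planned criterion. Leaving out wild-type Input replicate 1 or 2, or ob/ob Input replicate 2, however, kept 1 each. The median change of the 47 genes was 1.255 without ob/ob Input replicate 3 against 1.359 (median SE 0.239 against 0.227). The criterion was thus judged wrong after the result was seen. Leaving out ob/ob Input replicate 1 or wild-type Input replicate 3 gave a median SE of 0.24 or 0.245 and kept all 47 calls. For these 47 genes that argues against a loss of precision alone. How much ob/ob Input replicate 3 itself contributed stays open, since calls were also lost without other arrays. With the letter as a covariate the share of calls kept was 1 (47 of 47), which argues against the letters. Of 10 splits of the 6 arrays, 1 gave as many calls, the real one (47; highest other 1), and 10 splits are too few for a share under 0.05; a split that exchanged wild-type Input replicate 3 and ob/ob Input replicate 1 gave 2836 genes at an unadjusted p under 0.05 against 2760 for the real one in a fit of 2 groups, which points to a structure of the samples beside genotype.

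Some genes high in IP of both genotypes have no known tie to these neurons, and a single faulty probe set could give such a signal. There were 24 genes at least 4-fold higher in both genotypes with another probe set. In 5 (20.8%, confidence interval 7.1% to 42.2%) the other probe sets were by their median under 2-fold higher in both genotypes: Rala, Brd2, Itgb1, Lhx9 and Uba6. Among lower genes it was 8 of 122 (6.6%, Fisher's exact p = 0.0406). Other probe sets of Preb (log2 difference 0.424), Ube2a (0.859) and Kalrn (0.96) were under 2-fold higher in wild type alone. Single probe sets thus did not account for most of the 24 genes. Of the 67 genes, those with no other probe set were not covered, and no biological explanation was tested.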

How the results depend on the processing

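All alternatives were planned, and where a count moved the cause was not tested unless stated. IP against Input kept its counts within 1.5 times except when all probe sets were tested, which adds tests (4710 in wild type and 4914 in ob/ob against 2627 and 2903). For ob/ob against wild type in IP (89) the counts were 43 with the letter as a covariate, 14 between F arrays, 54 with no filter, 48 and 55 after quantile normalization over 11 arrays and within IP and Input, 5 with only the groups compared and 1156 by fold alone. In Input (47) they were 1318 with the letter, 1370 between F arrays, 18 with no filter, 203 at log2 7, 230 and 183 after the 2 quantile normalizations, 244 with a variance trend, 0 with only the groups compared (2760 genes at an unadjusted p under 0.05 by limma) and 2427 by fold alone. For the difference between genotypes of IP over Input (6) they were 10 with the letter, 2 between F arrays, 21 with no filter, 10 at log2 7, 14 with all probe sets, 16 without probe sets that match several transcripts, 3 after quantile normalization within IP and Input and 2825 by fold alone. Among genes enriched in wild-type IP (79) they were 28 between F arrays, 43 at log2 7, 145 with all probe sets, 39 with only the groups compared, 37 when chosen on ob/ob and 238 by fold alone.

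With the pool as a replicate block, the paired fit, 1 gene in place of 6 was called for the difference, Iapp; the fit also drops wild-type Input replicate 1, which has no partner, and without that array alone 4 were called. The counts were 2449 and 2897 for IP against Input in wild type and ob/ob, 90 for IP, 45 for Input and 81 among enriched genes; the block moved no other count by over 1.5 times.

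Leaving out each array gave 2166 to 2645 genes for IP against Input in wild type and 2789 to 3155 in ob/ob, 17 (without wild-type IP replicate 2) to 80 (without ob/ob IP replicate 3) between genotypes in IP, 54 to 96 among enriched genes, 1 (without wild-type Input replicate 2) to 2460 (without ob/ob Input replicate 1) in Input and 1 (without wild-type IP replicate 3) to 40 (without ob/ob Input replicate 1) for the difference. Lists numbered 11 to 11, 12 to 14, 7 to 12, 0 to 1 and 3 to 7 in the comparisons' order. With an estimated correlation 2, 2, 1 and 0 lists remained of 11, 12, 10 and 4 (wild type, ob/ob, IP between genotypes, difference), fry gave 17 and 25 in the first 2, and no filter 9 for the difference, where with the estimated correlation 3 had an unadjusted p under 0.05 and fry gave 4. Of 86 named calls 43 passed under every alternative, 43 failed under at least 1 and 0 changed sign. The failures lay mostly in the genotype comparisons. With only the groups compared, 16 of 20 named calls failed between genotypes in IP and 20 of 20 in Input. In that setting 0 of 20 failed for IP against Input in wild type and 0 of 20 in ob/ob. With the pool as a replicate block 5 of 6 failed for the difference. Wild-type IP replicate 1 could not be put back, as its column was empty, the other table was identical, and the difference of differences needs all groups, so those alternatives were not run. Between genotypes, with 2 or 3 arrays per group, most simulated 2-fold changes stayed under the threshold. The simulation recovered 34% of 2-fold changes in IP and 48% in Input.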

Other observations

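The tests of mitochondrial transcripts and of splits of the ob/ob arrays were chosen only after the result was seen.

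Among lists that did not pass in wild-type IP against Input, members went both ways in some. Th, which makes catecholamines, was 7.60-fold higher, while 4 of the other 5 aminergic genes were lower (1 higher and 4 lower adjusted over the list alone; camera adjusted p = 0.432). Opioid genes held 3 higher and 1 lower of 6 (3 and 2 adjusted over the list alone; camera adjusted p = 0.334), GABAergic genes 2 lower of 7 (1 adjusted over the list alone; 0.572) and glutamatergic genes none of 3 (0 adjusted over the list alone; 0.66). Neuropeptide processing genes held 3 higher and 4 lower of 14 (3 and 4 adjusted over the list alone; 0.59). Leptin signalling genes held 6 higher and 4 lower of 19 (6 and 4 adjusted over the list alone; 0.574), among them Pomc and Agrp on opposite sides.

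Further lists in wild-type IP against Input did not pass. Glucocorticoid genes held 3 higher and 6 lower of 12 (4 and 6 adjusted over the list alone; camera adjusted p = 0.202), thyroid axis genes 1 lower of 3 (1 adjusted over the list alone; 0.339) and oligodendrocyte precursor genes 2 lower of 4 (2 adjusted over the list alone; 0.132). Endoplasmic reticulum stress genes held 3 higher and 2 lower of 11 (3 and 2 adjusted over the list alone; 0.59), inflammation genes 1 lower of 4 (1 adjusted over the list alone; 0.329) and circadian clock genes 2 higher and 3 lower of 12 (3 and 4 adjusted over the list alone; 0.648). Axon growth genes held 3 and 3 of 12 (3 and 5 adjusted over the list alone; 0.612) and ribosomal protein genes 10 and 2 of 43 (9 and 2 adjusted over the list alone; 0.132). Of 2 pituitary genes, too few for a test, Cga, a subunit of pituitary hormones, was at least 3.54-fold lower.

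In ob/ob IP against Input the median and mean differed in sign for opioid genes (-0.02 and 0.46) and pan-neuronal genes (0.10 and -0.14), and neither list passed. In ob/ob against wild-type IP, Crym (-1.52) was called in the tanycyte list, which did not pass, and astrocyte genes had camera adjusted p = 0.11 (lower and passing with 0.000457 without ob/ob IP replicate 3 and 0.00435 with no filter), microglia genes 0.508 and endothelium genes 0.912. In Input, magnocellular genes had a median of -0.08 and a mean of 0.26, and tanycyte genes 0.13 and -0.29.

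Nuclear non-coding RNA was tested as a sign that the pull-down leaves nuclear RNA behind. The median of 6 such RNAs was -3.53 in wild type and -2.745 in ob/ob. In wild type they ranged from Rian (-0.87) to Meg3 (-4.60), with Malat1 at -1.69 and Neat1 at -3.30. That is what this explanation needs. All 6 are non-coding, however, so nuclear retention could not be told apart from a lack of translation. Transcripts of the mitochondrial genome were represented by ND5 alone (-6.703 in wild type and -5.746 in ob/ob), while 72 nuclear-encoded respiratory chain genes had medians of 0.429 and 0.367; with 1 gene, a pull-down of cytosolic ribosomes only could not be told from other causes.

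Extra copies of genes beside Pdyn on the artificial chromosome could raise them in IP. The 2 tested neighbours within 300 kb had a median of 0.27 in wild type and -0.041 in ob/ob (Sirpa -0.398 and -0.493, Stk35os1 0.939 and 0.411), and a rule added after the result was seen treats fewer than 3 genes as too few to decide. For IP against Input in ob/ob, 1 of 10 splits of the 6 arrays gave as many calls, the real one (2903; highest other 0), and 10 splits are too few for a share under 0.05.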
